A study of Homo sapiens with 33 samples.

How the data were processed

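The series holds 33 samples of the breast cancer cell line MCF-7 in 21 groups, of which 23 samples had values. These are 16 RNA-seq libraries and 7 lists of estrogen receptor alpha (ERα) peaks from chromatin immunoprecipitation (ChIP). The other 10 samples, which cover FOXA1, XRCC1, PARP1 and BRG1 ChIP, FAIRE-seq and an ERα sample with the inhibitor at 10 min, are not analysed here. For the RNA libraries, cells carried a control siRNA (siControl) or an siRNA against FEN1 (siFEN1) at 25 nM, were kept without hormone for 72 h, and received vehicle or 10 nM estradiol (E2). Each of these 4 groups had 4 libraries, numbered 1 to 4 in the labels. The time in E2 before RNA extraction is not given in the sources used here, nor is the hormone state of the siControl and siFEN1 ChIP samples. For the other ERα lists, per the labels, cells received 10 nM E2 for 10 or 30 min after 72 h without hormone, or were proliferating, with or without 100 nM of a FEN1 inhibitor.

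RNA values were deposited as a signal per gene and library: read counts that the authors had divided by DESeq2 normalization factors, as the name of the deposited table states. Salmon 0.14.1, DESeq2 and MACS are named, without roles, in the submitters' processing notes, together with the hg19 build. The annotation, the filters and the design of the authors' test are not given in the sources used here. Steps in the low values gave what 1 read is worth in each library, but 11.8% to 14.7% of the low values were whole multiples of it within 0.001 of a read. Whole reads could therefore not be recovered, the planned count tests were not run, and the values were tested on a log scale. Total normalized counts lay between 20.9 M and 22.7 M per library, and the read worth put the assigned reads at about 17.4 M to 31.3 M. Mitochondrial transcripts took 4.43% to 8.64% of each library. Reads were 65 bp long and the labels name a library kit that does not mark strand, so overlapping and antisense genes cannot be told apart. Genes with near-identical copies, such as histones and pseudogenes, are uncertain for the same kind of reason.

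Values were analysed in R 4.3.3 with limma 3.58.1 and version 1.17.8 of data.table. Of 28874 genes, the 18970 with at least 10 normalized counts in at least 4 libraries were tested, and 225 of those have no symbol. One fit of 4 group means was made to log2(value + 1) over all 16 libraries, with empirical Bayes moderation along a mean-variance trend and Benjamini-Hochberg adjustment, at an adjusted p of 0.05. All fold changes are on this log2(value + 1) scale, which understates the change of low genes. The 5 contrasts were E2 in siControl cells, E2 in siFEN1 cells, knockdown in vehicle, knockdown in E2, and the interaction. No library pair of a group matched within sampling noise, the lowest chi-square per degree of freedom being 2.18. The labels do not say that replicates were separate cultures, so p-values measure the spread between these samples, which may be technical.

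The replicate numbers paired the libraries. Deviations from the group means correlated at 0.34 to 0.50 between libraries of the same number, and 16 of 16 libraries correlated best with their own number. Replicates 1 and 2 on one side and 3 and 4 on the other also formed a pair of batches: the first principal component, with 34.6% of the variance, placed all 8 libraries of replicates 1 and 2 below 0 and all 8 of replicates 3 and 4 above it. Between libraries of different groups, the mean correlation was 0.395 within a batch, same-numbered libraries included, and -0.394 between batches. Much of the correlation between same-numbered libraries is therefore shared by the whole batch. The pairing is seen in the data and is not stated in the labels. A fit with the replicate number as a block is given beside results whose call it changes or whose count it moves by more than 1.5 times. For the counts over all genes, contrasts within either batch are given, worded as replicates 1 and 2 alone or 3 and 4 alone. They come from one fit to all 16 libraries with a mean per group and batch, so both batches share its estimate of the spread.

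The 21 gene lists were written before the data were examined: estrogen-induced genes, estrogen-repressed genes, DNA replication, mitosis, base excision repair, double-strand break repair, p53 targets, the ER complex, interferon response, integrated stress, cholesterol synthesis, ribosome biogenesis, the BCL2 family, luminal markers, basal and mesenchymal markers, blood and fibroblast markers, replication-dependent histones, mitochondrially encoded genes, housekeeping genes, immediate early genes, and the genes beside FEN1. Camera with a preset inter-gene correlation of 0.01 tested each list in each contrast, with adjustment over the 105 tests. Camera with an estimated correlation and fry, which asks whether the genes of a list move one way on balance, were alternatives. Named genes were FEN1, the 10 largest rises and 10 largest falls per contrast among genes past the threshold with a symbol in the annotation, a mean of at least 50 normalized counts and no overlap between the groups, up to 4 genes of each list with the smallest p, and 14 genes fixed beforehand. Genes from the blocked fit alone were chosen after their values were seen.

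The relative size of the E2 response was measured with held-out libraries. Genes were chosen in 2 replicates per siControl group, and the slope through 0 of siFEN1 on siControl log2 fold changes was taken against the other replicates. Noise in the siControl changes lowers this slope, so the slope in the reverse direction is given as well.

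On simulated data made from the real means and spreads, with about 67 genes changed per fold size among 18970 tested, the fit for the E2 contrast in siControl cells recovered 41.8% of 2-fold changes, or 61.2% with the block. For the knockdown contrast in vehicle, the shares were 37.3% and 67.2%, for knockdown in E2 52.2% and 65.7%, for E2 in siFEN1 cells 37.3% and 53.7%, and for the interaction 29.9% and 49.2%.

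Peaks were deposited with positions on hg19 and, in 4 lists, a score per peak from the authors' peak caller whose type is not given. The 2 lists from proliferating cells were deposited with a pileup signal at the summit instead, and the 10 min list with no score. Scores and pileups are the authors' own and were used only to rank peaks within a list. Each list came from 1 library, and calling thresholds are not given in the sources used here, so no test compares the ChIP conditions. A peak counted as kept when it overlapped a peak of the second list by at least 1 bp in bedtools 2.31.1. Shares carry 95% Wilson intervals, which cover counting error only, and 100 random shifts of the first list gave the background overlap. Genes and coordinates came from GENCODE 44 mapped to GRCh 37, the build also called hg19, which gave positions to 18745 tested genes. Promoters were taken as 1000 bp around a transcription start. Peaks within 20 kb of a start were counted per gene and compared with a two-sided Fisher's exact test, in a family of 28 tests.

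The estrogen response element GGTCANNNTGACC with up to 1 mismatch, and the forkhead element TGTTTAC, were searched in 250 bp around each peak centre and in windows shifted by 10 kb. For the lists from proliferating cells the deposited summit took the place of the peak centre, so element shares are not measured alike across all lists. These searches used samtools 1.23.1, pysam 0.24.0, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9. Alternative settings varied the pseudocount, the filter, the scaling, the variance model, the libraries fitted, the block, the fold minimum, the set test, the overlap rule, the score threshold, the window and the gene background. The tests and the named-gene rule were fixed before the data were examined. Contrasts within either batch, the search for elements, peaks near genes changed by the knockdown, peaks near fixed genes and kept shares near E2-regulated genes were added after seeing the data. What the element search in siFEN1-only peaks would show under either account was set down before the search was run.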

Results

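FEN1 is a nuclease that cuts flap structures in DNA replication and base excision repair, and MCF-7 is a breast cancer cell line whose growth depends on estrogen and its receptor ERα. The series asked how loss or inhibition of FEN1 affects ERα binding and estrogen-regulated transcription. RNA-seq covered siControl and siFEN1 cells in vehicle or E2, with 4 libraries in each of the 4 groups. ERα peak lists, 1 per condition, covered siControl and siFEN1 cells, cells at 10 or 30 min of E2, and proliferating cells, the last pair of settings also with a FEN1 inhibitor.

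FEN1 mRNA (ENSG00000168496.4, chromosome 11, 61560383 to 61564710, plus strand, GRCh37) was lower in every siFEN1 library than in every siControl library of the same hormone arm. In vehicle it stood at 900 ± 343 normalized counts with siControl and 219 ± 98.8 with siFEN1 (SD, n = 4). In E2 the levels were 1339 ± 254 and 347 ± 100 (SD, n = 4). The log2 fold changes were -2.07 (SE 0.33, limma adjusted p = 0.037, or 0.0054 with the replicate block) and -1.97 (SE 0.33, adjusted p = 0.046, or 0.0083 with the block). A two-sided exact permutation test gave p = 0.0286 in each arm, the smallest value that 4 libraries against 4 allow. The depth of the knockdown differed between replicate numbers. In vehicle, replicates 1 to 4 held 44.9%, 54.4%, 9.5% and 13.4% of the paired siControl level, and in E2 42.9%, 32.2%, 14.2% and 21.3%. The extra change in replicates 3 and 4 was -2.12 on the log2 scale in vehicle (SE 0.228, adjusted p = 0.0098) and -1.09 in E2 (adjusted p = 0.188). The call in E2 was lost whenever any 1 library was left out, and that in vehicle in 6 of 8 such fits.

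**Figure D1:**
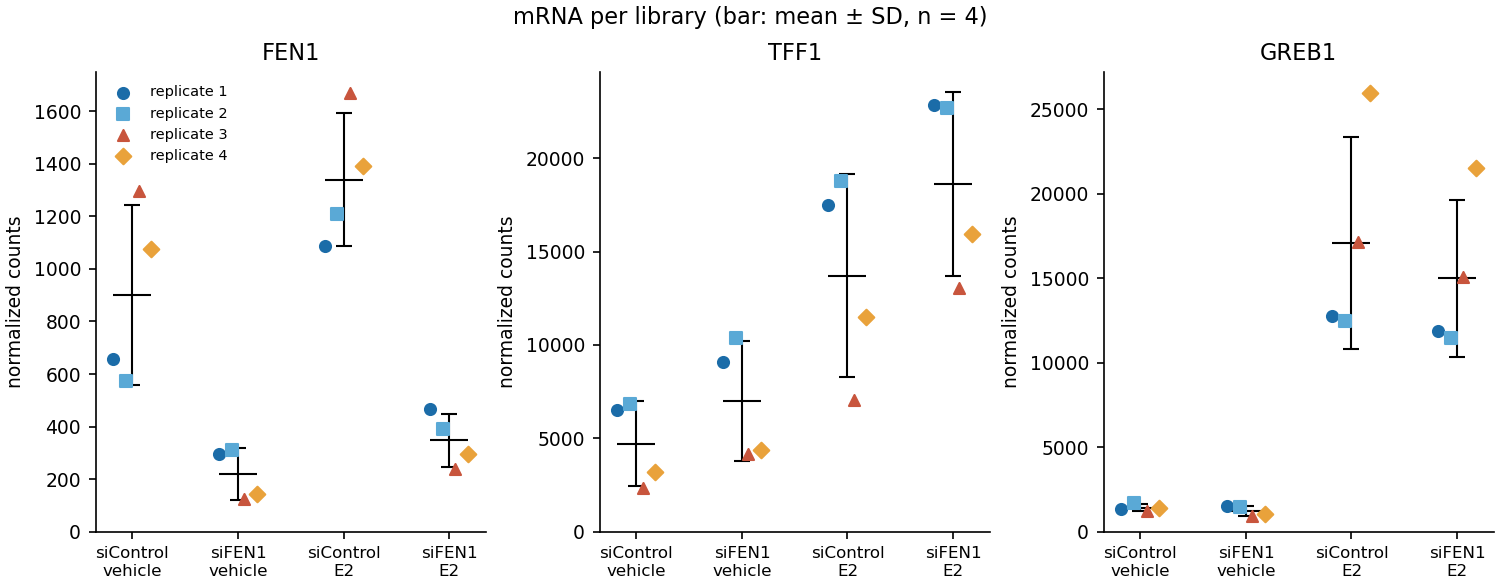
Normalized counts of FEN1, TFF1 and GREB1 in each of the 16 RNA libraries, by siRNA and hormone, with the mean and SD of 4 libraries per group. FEN1 lay at 219 and 347 on average with siFEN1, against 900 and 1339 with siControl, while GREB1 rose with E2 under both siRNAs.

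Estradiol changed a broad set of genes in siControl cells, classical targets of ERα among them. GREB1, an ERα cofactor and target, rose from 1421 ± 213 to 17081 ± 6284 normalized counts (SD, n = 4), a log2 fold change of 3.53 (SE 0.25, adjusted p = 2.3e-06). XBP1, a transcription factor of the unfolded protein response, rose from 11412 ± 922 to 34618 ± 3235 (1.60, adjusted p = 2.7e-07), and the secreted protein gene TFF1 rose from 4719 ± 2290 to 13710 ± 5448 (1.58, adjusted p = 0.041). Genes of ribosome assembly rose as a group, and ESR1, which encodes ERα, fell by 0.51 (adjusted p = 0.025). The interleukin receptor gene IL1R1 had the largest fall among the named genes, from 4288 ± 479 to 1304 ± 133 (-1.72, adjusted p = 0.00039).

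In all, limma called 571 genes higher and 197 lower with E2 in siControl cells. With the replicate block the counts were 1611 and 1215. Replicates 1 and 2 alone gave 1041 and 433, and replicates 3 and 4 alone 703 and 472. The 10 largest rises by the naming rule were LINC01016 (5.96), HCK (5.18), GREB1, FSIP1 (3.29), ENSG00000253125 (3.21; the annotation gives its identifier in place of a symbol), VXN (3.19), C5AR2 (3.12), AMZ1 (3.12), IFITM10 (3.09) and KRT13 (3.02). After IL1R1 the largest falls by the same rule were in COLEC10 (-1.60), HCAR3 (-1.58), PSCA (-1.47), FAR2P2 (-1.46), LINC02984 (-1.44), GRB7 (-1.41), SPRY1 (-1.41), AFF2 (-1.40) and DAB2 (-1.30). Among the genes fixed beforehand, MYC rose by 1.76 (adjusted p = 0.028), CCND1 by 0.88 (adjusted p = 0.017) and the chemokine gene CXCL12 by 2.37 (adjusted p = 0.016). The progesterone receptor gene PGR (3.23, adjusted p = 0.105), PDZK1 (2.03, adjusted p = 0.179), PCNA (0.55, adjusted p = 0.063) and PARP1 (0.29, adjusted p = 0.388) passed the threshold only with the block, at 0.00023, 0.0032, 0.0037 and 0.048. FOXA1 (-0.13), GATA3 (-0.04), XRCC1 (-0.19) and SMARCA4 (0.09) did not pass with or without it, and FEN1 itself stood at 0.63 (adjusted p = 0.42, or 0.27 with the block).

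Of 55 estrogen-induced genes, 38 rose and none fell in limma, where 43 rose adjusted over the list alone and 49 with the block. Their median was 1.46 (camera adjusted p = 4.6e-51, and adjusted p = 0.0053 with an estimated correlation). TPD52L1 (1.74), IGFBP4 (1.94), XBP1 and GREB1 had the smallest p. Of 30 estrogen-repressed genes, 6 fell and 2 rose (16 and 2 adjusted over the list alone, 23 and 3 with the block), with a median of -0.59 (adjusted p = 1.3e-08, and adjusted p = 0.011 with an estimated correlation, or 0.066 with both that and the block). CCNG2 (-0.94) and ERBB3 (-0.47) were among the falls, and SEMA3B rose by 0.91. Ribosome biogenesis genes rose in 23 of 29 cases (26 adjusted over the list alone, 28 with the block; median 0.73, adjusted p = 3.0e-32, and adjusted p = 0.0053 with an estimated correlation), with NOP56 at 1.00, RRS1 at 1.06, MRTO4 at 0.85 and NOP58 at 0.78.

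DNA replication genes rose in 14 of 52 cases (27 adjusted over the list alone, 28 with the block), with a median of 0.48 (camera adjusted p = 3.6e-19, but adjusted p = 0.10 with an estimated correlation). UHRF1 (1.07) and the helicase subunits MCM2 (0.89), MCM3 (0.75) and MCM7 (0.69) had the smallest p, and the largest rises past the threshold were MCM10 (1.15), UHRF1 and MCM6 (1.01). In base excision repair, UNG (0.80) and APTX (0.37) rose among 27 genes (4 adjusted over the list alone, 7 with the block), with a median of 0.23 (adjusted p = 0.00024, but adjusted p = 0.11 with an estimated correlation). In double-strand break repair, CHEK2 (0.87), ATRIP (0.93) and XRCC2 (0.72) rose among 32 genes (5 and 9 by the same measures), with a median of 0.27 (adjusted p = 4.0e-05, but adjusted p = 0.17 with an estimated correlation). None of 37 mitosis genes passed in limma (median 0.04, camera adjusted p = 0.92).

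The other lists had no camera call in siControl cells without the block. Genes past the threshold among them were AEN (0.85) and CDKN1A (-0.31) of 29 p53 targets, 3 that rose and 4 that fell of 35 ER complex genes including NRIP1 (1.04), TRIM24 (-0.59) and NCOA3 (-0.61), and 3 that rose and 1 that fell of 32 integrated stress genes including STC2 (1.81), SLC7A5 (1.32) and DDIT4 (-0.47). BCL2L1 fell by 0.56 in the BCL2 family of 15, KRT19 (0.41), CDH1 (0.45) and XBP1 rose and ESR1 fell among 20 luminal markers, and CD44 (1.34) and ITGB4 (-0.49) went apart among 14 basal and mesenchymal markers. HPRT1 (0.72) and TFRC (0.62) rose among 16 housekeeping genes, and EGR3 (2.24) and MYC among 21 immediate early genes. No gene passed in limma in the interferon (35 genes, median -0.36), cholesterol (23, 0.04), histone (10, -0.09), mitochondrial (13, -0.22), blood and fibroblast (5, 0.64) or FEN1-neighbour (7, 0.06) lists. With the block, rises and falls numbered 3 and 6 for p53 targets, 6 and 6 for the ER complex, 1 and 4 for interferon, 11 and 1 for integrated stress, 3 and 3 for cholesterol, 1 and 5 for the BCL2 family, 4 and 5 for luminal, 2 and 2 for basal and mesenchymal, 3 and 1 for housekeeping and 5 and 2 for immediate early genes. In the same fit, camera called integrated stress higher (adjusted p = 0.00014) and interferon (0.019), the BCL2 family (0.029) and mitochondrial transcripts (0.023) lower, and none of these held with an estimated correlation, at adjusted p = 0.15 to 0.93. The mean log2 level of the mitochondrial list fell most in replicate 4, from 15.6 in vehicle to 14.9 in E2. In replicate 3 it rose from 15.5 to 15.6.

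**Figure D2:**
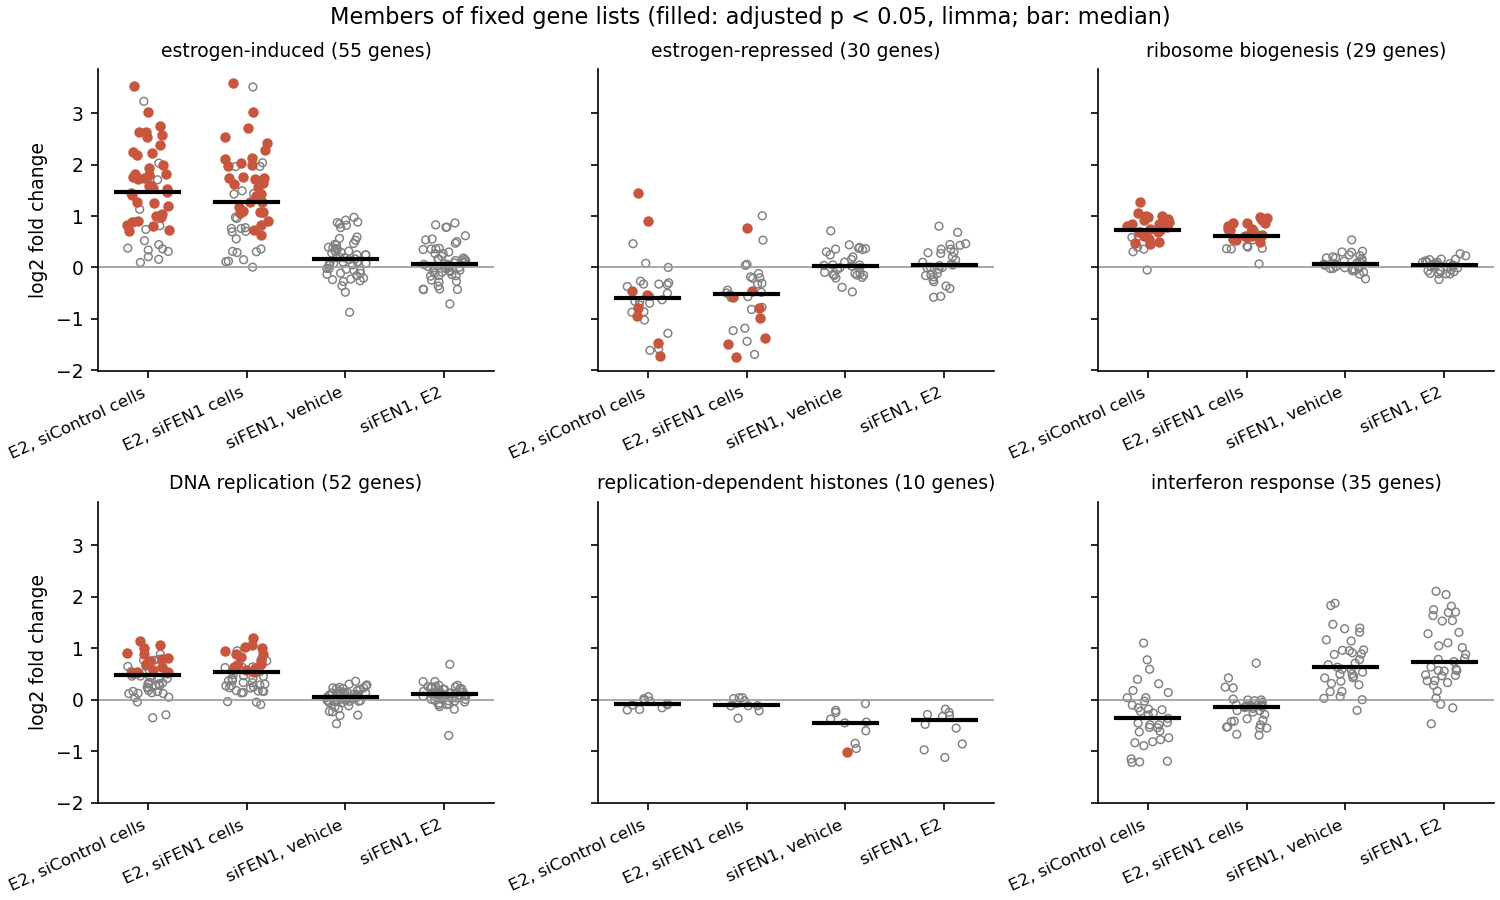
Log2 fold changes of the tested genes of 6 fixed lists in the 4 two-group contrasts, 1 point per gene with the list median. Estrogen-induced genes had medians of 1.46 and 1.27 for E2 in siControl and siFEN1 cells, against 0.17 and 0.06 for the knockdown.

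The E2 response of siFEN1 cells answers whether cells with less FEN1 still respond to hormone. GREB1 rose from 1237 ± 316 to 14995 ± 4635 normalized counts (SD, n = 4; log2 fold change 3.59, SE 0.25, adjusted p = 2.5e-06), XBP1 from 11806 ± 784 to 31002 ± 2166 (1.39, adjusted p = 1.2e-06) and IL1R1 fell by 1.74 (adjusted p = 0.0004). Estrogen-induced and ribosome biogenesis genes were higher as groups, and estrogen-repressed genes lower. The counts were 453 higher and 161 lower, or 1539 and 1206 with the block, 462 and 242 in replicates 1 and 2 alone, and 835 and 466 in replicates 3 and 4 alone. Without 1 library the total of 614 lay between 351 and 449. By the naming rule, the largest rises besides GREB1 were LINC01016 (5.39), SDK2 (4.18), HCK (3.95), RBM24 (3.18), KRT13 (3.03), C5AR2 (2.99), SLC47A1 (2.78), MYBL1 (2.72) and CYP26B1 (2.63). The largest falls by that rule, which passes over genes whose groups overlap, were HCAR2 (-1.91), IL1R1, PI4KAP2 (-1.62), ATP6V0A4 (-1.56), VAT1L (-1.54), ATP13A4 (-1.50), PSCA (-1.49), FAR2P2 (-1.38), BLNK (-1.38) and MAB21L4 (-1.32). PCNA rose by 0.63 (adjusted p = 0.039). TFF1 (1.49, adjusted p = 0.062), MYC (1.43, adjusted p = 0.088), CCND1 (0.70, adjusted p = 0.066), CXCL12 (1.97, adjusted p = 0.054), PGR (3.51, adjusted p = 0.081), PDZK1 (2.04, adjusted p = 0.187), PARP1 (0.43, adjusted p = 0.138) and FOXA1 (-0.26, adjusted p = 0.82) passed only with the block, between 7.8e-06 and 0.0063. ESR1 (-0.25, adjusted p = 0.36) did not pass.

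In siFEN1 cells, 31 of 55 estrogen-induced genes rose with E2 (43 adjusted over the list alone, 49 with the block; median 1.27, camera adjusted p = 1.3e-48, and adjusted p = 0.0053 with an estimated correlation). Of the estrogen-repressed genes, 7 fell and 1 rose (12 and 2 adjusted over the list alone, 20 and 3 with the block; median -0.52, adjusted p = 2.8e-08, and adjusted p = 0.011 with an estimated correlation, or 0.068 with the block as well). Ribosome biogenesis genes rose in 20 of 29 cases (25 adjusted over the list alone, 28 with the block; median 0.62), with adjusted p = 0.0053 with an estimated correlation. Replication genes rose in 16 of 52 (29 adjusted over the list alone, 30 with the block; median 0.54, but adjusted p = 0.070 with an estimated correlation), among them GINS2 (0.89). UNG (0.80) and PCNA rose in base excision repair (2 adjusted over the list alone, 7 with the block; median 0.17, camera adjusted p = 0.0011, but adjusted p = 0.16 with an estimated correlation). In double-strand break repair BRCA1 (0.72), CHEK2 (0.96), XRCC2 (0.78), ATRIP (0.73) and EXO1 (0.67) rose (7 adjusted over the list alone, 13 with the block; median 0.32, camera adjusted p = 4.7e-07, but adjusted p = 0.10 with an estimated correlation). Genes past the threshold in lists without a camera call were CDKN1A (-0.35) and TRIAP1 (0.45) of the p53 targets, 3 that rose and 3 that fell of the ER complex including NRIP1 (1.08) and NCOA3 (-0.54), and STC2 (1.76), XBP1 and DDIT4 (-0.49) of integrated stress. BCL2L1 (-0.45) and ITGB4 (-0.52) fell and KRT19 (0.40), CD44 (1.20), HPRT1 (0.69) and EGR3 (2.00) rose in theirs. No gene passed in limma in the mitosis (median 0.10), interferon (-0.14), cholesterol (0.01), histone (-0.09), mitochondrial (-0.18), blood and fibroblast (-0.10) or FEN1-neighbour (0.06) lists. With the block, rises and falls numbered 2 and 6 for p53 targets, 6 and 5 for the ER complex, 0 and 1 for interferon, 7 and 1 for integrated stress, 1 and 1 for cholesterol, 2 and 6 for the BCL2 family, 3 and 6 for luminal, 3 and 1 for basal and mesenchymal, 0 and 1 for histone, 3 and 0 for housekeeping and 3 and 4 for immediate early genes, and 1 and 0 for FEN1 neighbours. With the block alone, camera also called integrated stress higher (0.013) and the BCL2 family (0.016) and mitochondrial transcripts (0.036) lower, none with an estimated correlation (adjusted p = 0.10 to 0.93). The mitochondrial list again fell most in replicate 4, from a mean log2 level of 15.6 in vehicle to 15.1 in E2.

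No gene passed the threshold in limma for a different E2 response in siFEN1 and siControl cells, where 227 of 18970 genes had an unadjusted p under 0.05. With the replicate block the count was also 0, with 683 at an unadjusted p under 0.05, and replicates 1 and 2 alone gave 2 genes, as did replicates 3 and 4 alone. Both 227 and 683 are below the share of 0.05 that chance alone would give. In simulated data 29.9% of 2-fold interactions were recovered, or 49.2% with the block, so real differences may be missed. The interaction was 0.06 for GREB1 (SE 0.36), -0.09 for TFF1 (SE 0.58), 0.28 for PGR (SE 1.4) and 0.10 for FEN1 (SE 0.47), each with an adjusted p of 1.0. Across genes, which are not independent replicates, the E2 fold changes under both siRNAs correlated at r = 0.556. Of 768 genes called in siControl cells, 764 had the same sign in siFEN1 cells, 361 rose and 107 fell in both, and none was called in opposite directions. Independent lists of these sizes would share 13.6 and 1.67 genes. On held-out libraries the slope of the siFEN1 on the siControl response was 0.870 over 1881 genes, from the 1 of 6 replicate choices that called enough genes. The slope of the siControl on the siFEN1 response over the same genes was 0.872, and the median ratio of siFEN1 to siControl changes was 1.045, so the slope does not show a smaller response in siFEN1 cells. With the block it was 0.823 on average over 6 choices (range 0.699 to 0.914), and 0.997 in the reverse direction. No list passed camera for the interaction. With the block alone, estrogen-induced genes (median -0.09, adjusted p = 0.0078), immediate early genes (-0.11, 0.020) and integrated stress genes (-0.07, 0.023) did, but at adjusted p = 0.93, 0.74 and 0.93 with an estimated correlation. Of the 55 estrogen-induced genes, 13 had an interaction above 0.

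FEN1 knockdown itself changed few genes without the block. In vehicle, NELL2, a secreted neural protein gene, went from 551 ± 97.0 to 127 ± 51.5 normalized counts (SD, n = 4), a log2 fold change of -2.20 (SE 0.36, adjusted p = 0.037), and in E2 from 331 ± 56.0 to 59.6 ± 26.2 (-2.58, adjusted p = 0.019). TIMP2, an inhibitor of matrix metalloproteinases, rose by 0.83 in vehicle (adjusted p = 0.023) and 0.86 in E2 (adjusted p = 0.019). The histone genes H1-2 (-1.01, vehicle) and H2AC25 (-0.66 in vehicle, -0.78 in E2) fell, and the cell-cycle inhibitor gene CDKN1A rose by 0.47 in vehicle (adjusted p = 0.039), and passed in E2 only with the block (0.43, adjusted p = 0.09, or 0.0013). None of the estrogen-regulated genes fixed beforehand changed with the knockdown in limma, and GREB1 stood at -0.23 in vehicle (adjusted p = 1.0) and -0.17 in E2 (adjusted p = 1.0). TFF1, at 0.59 (adjusted p = 0.90) and 0.50 (adjusted p = 1.0), passed only with the block (0.015 and 0.037), and CCND1 in vehicle likewise (0.39, adjusted p = 0.75, or 0.039). ESR1 was at -0.35 in vehicle (adjusted p = 0.44) and -0.09 in E2 (adjusted p = 1.0).

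In vehicle 16 genes rose and 11 fell with siFEN1, and in E2 5 rose and 6 fell. With the block the counts were 530 and 342, and 421 and 282. Replicates 1 and 2 alone gave 118 and 30 in vehicle and 70 and 45 in E2, and replicates 3 and 4 alone gave 195 and 140, and 231 and 123. Without 1 library the total in vehicle lay between 0 and 10 and in E2 between 1 and 5. The largest rises in vehicle by the naming rule were GEMIN5 (1.49), TRIM47 (1.28), ZCCHC24 (1.05), IGFBPL1 (0.96), ARHGDIG (0.94), TIMP2, MBNL1 (0.79), PEDS1 (0.78), RMI2 (0.75) and DDIT4 (0.68). Besides NELL2, FEN1 and the histone genes, the falls were SLC1A1 (-1.84), CSTA (-1.24), USP46 (-0.83), GCNT4 (-0.82), AK3 (-0.71), TCAIM (-0.66) and DTD2 (-0.66), the last outside the naming rule and chosen after its value was seen. In E2 the rises were TGFBR2 (0.99), TIMP2, P4HA2 (0.72), PEDS1 (0.71) and CUEDC1 (0.51), and the falls besides NELL2, FEN1 and H2AC25 were CSTA (-1.29) and AK3 (-0.81). CENPS-CORT (-3.83), a read-through transcript, also fell in E2 and was chosen after its value was seen, since it lies outside the naming rule. Both arms called 3 of the same rises and 5 of the same falls, and all 27 genes called in vehicle had the same sign in E2. With the block, 274 rises and 173 falls were shared, against 11.8 and 5.08 for independent lists, and none was opposite. The arms have no library in common, but paired replicates link them. Across genes their fold changes correlated at r = 0.336.

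Replication-dependent histone genes were lower with siFEN1 in all 8 pairs of libraries, by 0.527 ± 0.116 on the log2 scale (mean and SD over 8 pairs). Of 28 genes in this list 10 were tested. The histone gene H2AC25, which passed in limma in both arms, is not in the list. H1-2 fell in vehicle, the only 1 of 10 in limma over all genes, and none passed in E2 (3 fell in each arm adjusted over the list alone, and 5 and 4 with the block, with H1-2 in E2 at -0.98 (adjusted p = 0.067, or 0.00012), H2BC21 at -0.85 and -0.86 and H2AC6 at -0.44 and -0.55). The medians were -0.44 (camera adjusted p = 6.6e-08) and -0.40 (adjusted p = 1.7e-08). With an estimated correlation these were adjusted p = 0.11 and adjusted p = 0.10, or 0.0032 in both arms with the block as well. Most of these mRNAs lack a poly(A) tail, so their measured level also depends on how RNA was selected.

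Interferon-response genes had a median of 0.63 in vehicle and 0.74 in E2 with siFEN1 (camera adjusted p = 3.4e-06 and 1.3e-08, but adjusted p = 0.99 and adjusted p = 0.85 with an estimated correlation). None of the 35 passed over all genes in limma, and 0 and 1 rose adjusted over the list alone. With the block 5 and 6 rose, among them IFI27 (1.88 and 2.11), SAMD9 (1.14 and 1.54) and STAT1 (0.43 and 0.48), with OAS1 (2.04) in E2, all chosen after their values were seen. The list median was 0.02 in replicates 1 and 2 and 1.16 in replicates 3 and 4 in vehicle, and 0.26 and 1.08 in E2, the same replicates in which FEN1 was lower. Of the markers of blood and fibroblast cells, 5 were tested, with medians of -0.24 and 0.08.

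**Figure D3:**
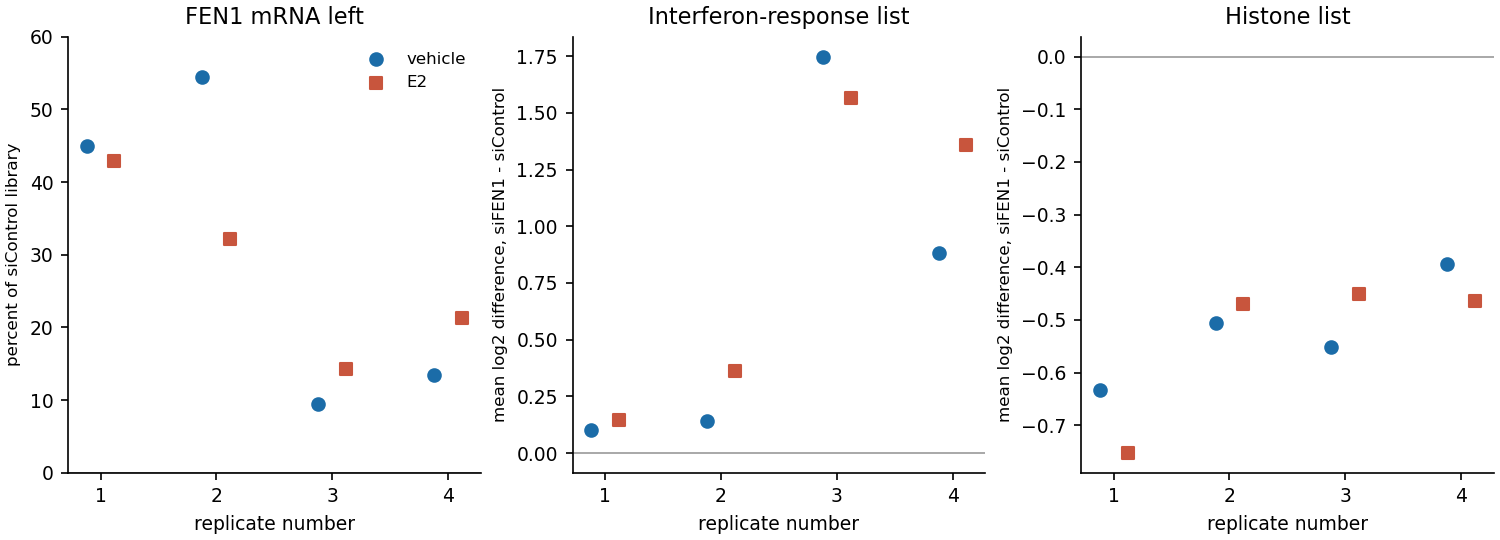
FEN1 mRNA left in the siFEN1 library as a percentage of the siControl library of the same replicate and hormone, and the mean log2 difference of the interferon and histone lists, for each of the 8 pairs. Histone differences lay between -0.75 and -0.39 in all pairs, and interferon differences were 0.10 to 0.36 in replicates 1 and 2 and 0.88 to 1.75 in replicates 3 and 4.

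Other lists had smaller medians with the knockdown. In vehicle, estrogen-induced genes (median 0.17, camera adjusted p = 0.0093) and immediate early genes (0.21, adjusted p = 0.0077) were called higher by camera, with no gene past the threshold over all genes in limma. With an estimated correlation these were adjusted p = 0.99 and adjusted p = 0.10. With the block 11 of the estrogen-induced genes rose and 1 fell in vehicle, and 4 and 1 in E2. SLC26A2 (0.88 and 0.78) and AREG (0.85 and 0.87) rose and SLC39A6 (-0.48 and -0.43) fell, all chosen after their values were seen. In E2, replication genes (median 0.11, camera adjusted p = 0.010, but adjusted p = 0.99 with an estimated correlation) and basal and mesenchymal markers (0.27, adjusted p = 0.0498, but adjusted p = 0.34 with an estimated correlation) were called higher. With the block alone camera also called integrated stress (0.038), cholesterol synthesis (0.016) and basal markers (0.012) in vehicle, and cholesterol synthesis (0.015), mitochondrial transcripts (0.021) and immediate early genes (0.044) in E2, at adjusted p = 0.10 to 0.93 with an estimated correlation. CDKN1A among p53 targets, DDIT4 among integrated stress genes and FEN1 among its neighbours were the only other list genes past the threshold in vehicle. In E2, FEN1 was the only list gene past the threshold in limma. Mitosis (median 0.04 in vehicle and 0.05 in E2), base excision repair (0.04 and 0.03), double-strand break repair (-0.02 and 0.00), ER complex (-0.06 and -0.06), estrogen-repressed (0.03 and 0.04), ribosome biogenesis (0.07 and 0.05), BCL2 family (0.08 and 0.04), luminal (0.02 and 0.01) and housekeeping genes (0.01 and 0.09) had no gene past it in either arm. The mitosis medians went opposite ways in the 2 batches. They were 0.36 in replicates 1 and 2 and -0.28 in replicates 3 and 4 in vehicle, and 0.26 and -0.17 in E2. The block changed which of these and other lists had genes past the threshold. In vehicle it gave 3 rises of estrogen-repressed genes, 4 each of luminal and immediate early genes, 2 of basal markers and 1 each of replication, cholesterol and ribosome genes, 2 rises and 1 fall of p53 targets, and falls of 2 housekeeping, 1 ER complex and 1 BCL2 family gene. In E2 it gave 2 rises each of estrogen-repressed, cholesterol and luminal genes and 1 each of integrated stress, basal and immediate early genes, 2 rises and 2 falls of p53 targets, 1 and 1 of the BCL2 family and of FEN1 and its neighbours, and falls of 2 housekeeping and 1 ER complex gene.

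ERα peaks were fewer after FEN1 knockdown. The siControl list held 27599 peaks over 24.2 Mb and the siFEN1 list 14299 over 14.7 Mb. The siFEN1 list kept 12062 of the siControl peaks, or 43.7% (95% interval 43.1% to 44.3%), against 1.15% for shifted peaks, and 3103 siFEN1 peaks had no siControl counterpart. Kept peaks were the high-scoring ones, with 18.6% kept in the lowest 10% of scores and 98.5% in the highest. Within 20 kb of its start TFF1 had 6 siControl and 3 siFEN1 peaks, ESR1 7 and 2, FOXA1 6 and 4, GREB1 2 and 1, CCND1 2 and 1, MYC 1 and 0, SMARCA4 1 and 0, PDZK1 4 and 4, and FEN1 1 and 1. PGR, CXCL12, GATA3, XRCC1, PARP1 and PCNA had 0 in both lists. The highest-scoring kept peaks lay on chromosome 14 at 95102729 to 95103751 (intergenic, nearest to SERPINA13P), in an intron of TNFSF8 on chromosome 9 at 117670182 to 117671043, and on chromosome 5 at 172881146 to 172883658 (intergenic). The highest-scoring peaks without a siFEN1 counterpart were intergenic, on chromosome 12 at 60928301 to 60929855 and 61303945 to 61305049 and on chromosome 1 at 188862108 to 188863473. An estrogen response element lay in 9.39% of kept peaks, 7.08% of those lacking and 1.42% of the siFEN1-only peaks. Of siFEN1-only peaks, 73.5% lay on chromosomes 1, 3, 17 and 20, against 36.0% of kept peaks and 22.4% of those lacking. Scores and depths of single libraries limit all of these shares, and the same number of top-scoring peaks from both lists gave 65.9% kept.

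Fewer ERα peaks were called with the FEN1 inhibitor in both settings. With 1 library per condition, a weaker inhibitor library and a change of binding cannot be told apart. At 30 min of E2 the vehicle list held 3767 peaks and the inhibitor list 1093, which kept 1024 or 27.2% (25.8% to 28.6%), against 0.0157% for shifted peaks. In proliferating cells 16799 peaks with vehicle and 5010 with the inhibitor shared 4909 of the former, or 29.2% (28.5% to 29.9%), against 0.168% shifted. In the reverse direction 94.2% and 96.6% of the inhibitor peaks had a vehicle counterpart. Kept shares rose from 3.45% in the lowest 10% of scores to 99.7% in the highest at 30 min, and from 1.37% to 96.0% by pileup in proliferating cells. The 3 highest-scoring peaks kept at 30 min were the TFF1 enhancer region in an intron of TMPRSS3 (chromosome 21, 43796412 to 43796820), an intron of NOXRED1 (chromosome 14, 77866554 to 77866984) and an intron of GREB1 (chromosome 2, 11638669 to 11639043). The highest lacking ones were intergenic on chromosome 3 at 168588599 to 168588912, in NT5C2 on chromosome 10 at 105001313 to 105001609, and in CLMN on chromosome 14 at 95663987 to 95664327. In proliferating cells, top pileups lay on chromosome 1 at 121483917 to 121485577, on chromosome 7 at 61968486 to 61969824 and in BRIP1 on chromosome 17 at 59800289 to 59801240, and the highest lacking ones on chromosome 16 at 46407514 to 46407918, on chromosome 10 at 42392519 to 42392923 and on chromosome 2 at 92308876 to 92309287. Apart from the BRIP1 peak these were intergenic, 162425 to 545654 bp from the nearest gene start. No peaks were removed here as lying in regions prone to false calls, so these need not be ERα sites. The estrogen response element lay in 27.1% of kept and 19.9% of lacking peaks at 30 min, and in 14.5% and 7.06% in proliferating cells. Forkhead elements were rarer in kept than in lacking peaks after knockdown, at 7.90% against 10.9%, and in proliferating cells, at 12.4% against 14.9%. At 30 min the shares were 9.28% (95% interval 7.65% to 11.2%) and 11.1% (9.96% to 12.3%), with overlapping intervals. With the same number of top-scoring peaks from both lists, 72.6% and 75.7% were kept.

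**Figure D4:**
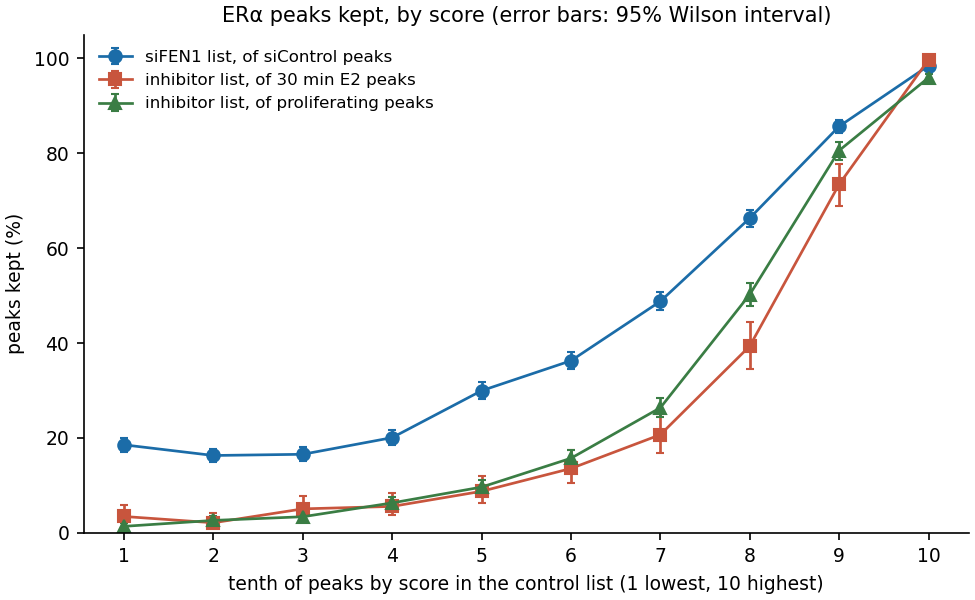
Percentage of the control or vehicle ERα peaks that overlapped a peak of the siFEN1 or inhibitor list, by the rank of the peak's own score or pileup in steps of 10%, with 95% Wilson intervals. Shares rose from 18.6%, 3.45% and 1.37% in the lowest 10% to 98.5%, 99.7% and 96.0% in the highest.

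Peaks at 10 min of E2 were mostly called again at 30 min. Of 1702 peaks, 1536 or 90.2% (88.7% to 91.6%) overlapped the 30 min vehicle list, against 0.122% for shifted peaks, and 41.9% of the 30 min peaks overlapped a 10 min peak. An estrogen response element lay in 21.2% of the shared 10 min peaks and 6.02% of the others. The 10 min peaks had a median width of 652.5 bp and the 30 min peaks of 229 bp, and the shared part was at least 50% of both peaks in only 31.6%. No score came with the 10 min list, so no ranking was possible.

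E2-regulated genes had ERα peaks near them more often than other genes. Of 569 E2-induced genes with a position, 50.8% had a siControl peak within 20 kb of the start, against 34.9% of 17980 other tested genes (odds ratio 1.93, two-sided Fisher's exact p = 2.3e-14, adjusted over 28 tests 5.8e-14). Of 196 E2-repressed genes the share was 51.5% (odds ratio 1.99, exact p = 2.5e-06, adjusted 4.1e-06). Genes share peaks with their neighbours, so they are not independent. At 30 min of E2 the peaks were near 26.9% of induced genes (odds ratio 4.30, exact p = 5.3e-40) and 6.63% of repressed genes (odds ratio 0.831, p = 0.595), against 7.88% of the others. With the inhibitor at 30 min the shares were 13.5% of induced genes (odds ratio 7.15) and 1.02% of repressed genes (odds ratio 0.471, exact p = 0.449). The siFEN1 list lay near 35.0% of induced (odds ratio 2.27) and 22.4% of repressed genes (odds ratio 1.22, exact p = 0.237), and the 10 min list near 16.9% (odds ratio 4.81) and 4.08% (odds ratio 1.01, p = 0.856). In proliferating cells the shares were 39.0% and 39.3% with vehicle (odds ratios 2.23 and 2.25) and 23% and 9.18% with the inhibitor (odds ratios 4.01 and 1.36, the latter exact p = 0.205). Of the fixed lists, 74.5% of estrogen-induced and 66.7% of estrogen-repressed genes had a siControl peak within 20 kb, and 54.5% and 36.7% a siFEN1 peak.

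**Figure D5:**
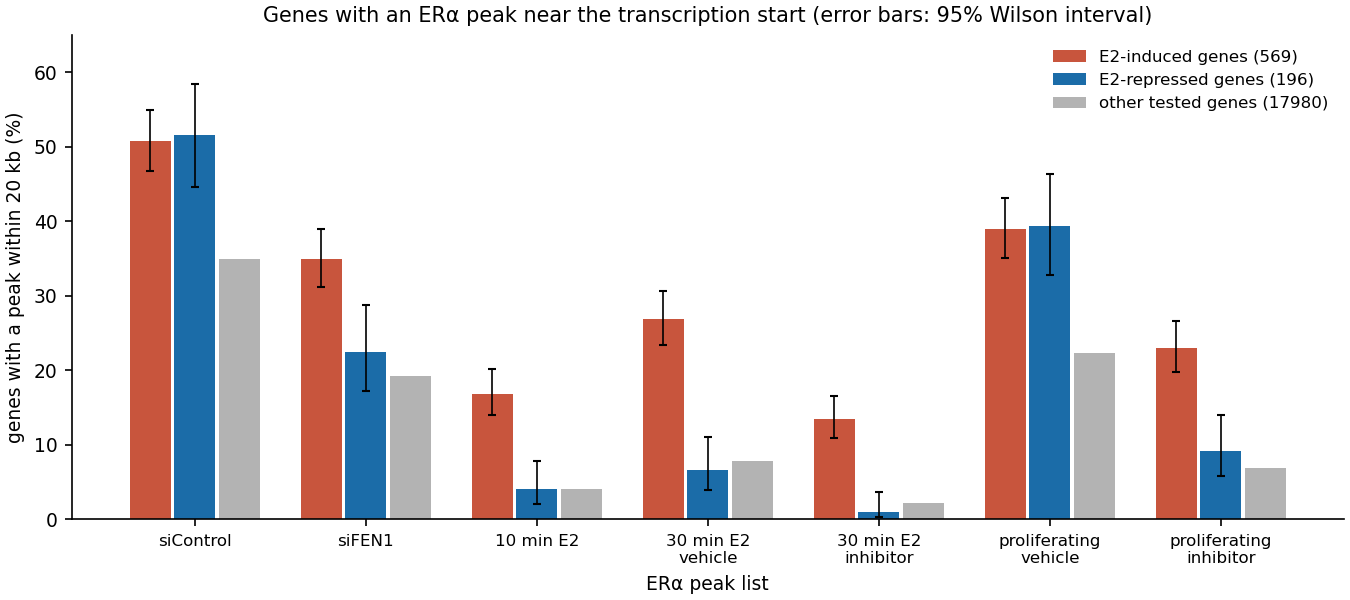
Percentage of E2-induced, E2-repressed and other tested genes with an ERα peak within 20 kb of the transcription start, for each of the 7 peak lists, with 95% Wilson intervals. Induced genes had 50.8% with the siControl list and 26.9% with the 30 min vehicle list, against 34.9% and 7.88% of other genes.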

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

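Tests of interferon genes, of the knockdown depth and of splits by gene counts were chosen after the results were seen, while the splits by lists were chosen before. The 3 peak tests were chosen before their own values were seen, the element search among them after other peak values had been seen.

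Of 448 groups of 4 libraries tested, over 107 genes and 5 library measures, 28 had a library far from the other 3 by Dixon's test at the 95% level. Chance alone marks about 1 in 20 groups. In siControl vehicle replicate 3, AEN stood high at 1408 normalized counts (next 754) and CCNG2 at 3567 (next 3186). Replicate 4 of that group was high for PGR at 279 (next 41.3), CXCL12 at 262 (next 128), IL1R1 at 4997 (next 4114) and MYBL1 at 256 (next 133), and replicate 2 for FSIP1 at 51.3 (next 10.9). In siControl E2, replicate 4 was high for CD44 at 4691 and IGFBP4 at 19601 and low for DAB2 at 307 (next 564). Replicate 3 of siControl E2 was low for IGFBPL1 at 60.6 and MBNL1 at 1308 and high for PCNA at 2081, and replicate 2 was high for P4HA2 at 536. In siFEN1 vehicle, replicate 4 was high for CD44 at 2032, CYP26B1 at 304 and STC2 at 8825. Replicate 3 of siFEN1 vehicle was low for KRT13 at 18.2 and high for NOP58 at 1363, and replicate 2 was high for SDK2 at 37.4 and SLC1A1 at 51.2. In siFEN1 E2, replicate 4 was low for PSCA at 230 and high for SLC47A1 at 326 and SLC7A5 at 6910, and replicate 3 was low for KRT13 at 275 and high for TRIM47 at 381. The mitochondrial share was low in siControl E2 replicate 4 at 4.43% (next 7.27%), and the share of the top 10 genes was low in siFEN1 E2 replicate 4 at 6.71% (next 8.40%).

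With the replicate block, 3 lists differed between siFEN1 and siControl cells in their E2 response by camera: estrogen-induced genes (adjusted p = 0.0078), immediate early genes (adjusted p = 0.020) and integrated stress genes (adjusted p = 0.023). None of the 3 passed without the block or with an estimated correlation.

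Fewer ERα peaks were called after FEN1 knockdown, and 3 hypotheses were tested. A weaker siFEN1 library could give this pattern, since the kept share was 79.9 percentage points higher in the highest than in the lowest 10% of scores. Calls in amplified regions as the whole account are argued against, since siFEN1-only peaks still held the estrogen response element at 2.93 times the rate of shifted windows, although their high share on chromosomes 1, 3, 17 and 20 had been seen when those were chosen. The element lay in 1.42% of siFEN1-only peaks against 9.39% of kept peaks, so most siFEN1-only peaks may still be such calls. A change of binding shared with the inhibitor stays open: at equal scores, control peaks without a siFEN1 peak lacked an inhibitor counterpart 3.88 percentage points more often (SE 1.06). This value exceeded the bound of 2 set beforehand, and the demand for a margin over its SE was added after it was seen, so it and a weaker library cannot be told apart with 1 library per condition.

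Interferon genes were called higher with siFEN1 by camera, mostly in replicates 3 and 4, but not with an estimated correlation (adjusted p = 0.99 in vehicle and adjusted p = 0.85 in E2). None of 35 passed alone in limma without the block, and 5 in vehicle and 6 in E2 rose with it. If the rise is real, a response to transfection that varies between pairs may give this, with an SD over the 8 pairs of 0.878 times the mean, and a response that scales with the knockdown may as well, with a difference between replicates 3 and 4 and replicates 1 and 2 of 1.20. The replicates with less FEN1 are also 1 of the 2 batches, so these cannot be told apart, and an exact permutation of whole replicates gave p = 0.333, the smallest possible. A rank correlation over the 8 pairs was planned first and replaced, since FEN1 left fell in 2 clusters, and a permutation over the 8 pairs as if independent gave way to whole replicates. The 5 blood and fibroblast markers tested lie near the floor, so cells of another type were not tested.

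FEN1 was reduced more deeply in replicates 3 and 4, an extra change that passed in limma in vehicle but not in E2 (adjusted p = 0.188). In vehicle, library depth or normalization as a cause is argued against, since the replication list had a median extra change of 0.193 times that of FEN1 (bootstrap 0.128 to 0.228, bound 0.25). The bootstrap covers the spread between genes of the list and not that between libraries. Over all genes the median extra change in vehicle was -0.013, against -2.12 for FEN1. This cause was not tested in E2. A fuller knockdown with larger changes downstream stays open as a hypothesis: the part of the knockdown changes shared by both hormone arms was 1.13 times as large in replicates 3 and 4 as in 1 and 2, with 0.244, 0.235, 0.324 and 0.232 in replicates 1 to 4. The first form of this test, on genes called with the block, was replaced because those genes were chosen for alike changes across replicates. The batch and the depth of knockdown cannot be told apart here.

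For each two-group contrast, 2 of the 35 splits of the 8 libraries gave as many genes, the real one and that of replicates 1 and 2 against 3 and 4. The batch split is among the 35 in each contrast and gave more genes than the real one. With it the share cannot fall under 0.05, so this count cannot decide about chance. The real and highest other values were 768 and 2978 for E2 in siControl cells, 614 and 2822 for E2 in siFEN1 cells, 27 and 4599 for knockdown in vehicle, and 11 and 1416 for knockdown in E2. The split between the batches shows a structure of the samples. With the replicate block only the 8 splits that part all pairs can be compared, too few for a share under 0.05. There the real split was the 1 of 8 with as many genes in each contrast, at 2826, 2745, 872 and 703 with a highest other value of 0. For the interaction, siRNA labels were swapped inside pairs of the same number and hormone. At an unadjusted p under 0.05, 74 of 100 swaps gave as many genes (real 227, highest other 2298), and 58 of 100 with the block (real 683, highest other 4936), so chance could not be excluded. The highest swap turned all 4 vehicle pairs and no E2 pair, which counts the knockdown effect as an interaction, so these swaps are not free of real effects. By lists past camera within a contrast, 24, 24, 31 and 24 of the 35 splits gave as many, with real values of 7, 6, 4 and 4 and highest other values of 11, 12, 12 and 10, so chance could not be excluded for the number of lists. Of the 8 splits that part all pairs, 4, 4, 6 and 1 gave as many lists, with highest other values of 8, 7, 10 and 3.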

How the results depend on the processing

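The contrasts within replicates 1 and 2 and within 3 and 4, and blocked gene sets near peaks, were chosen after the results were seen, and the other settings before. The 2 count tests were not run, since whole reads could not be recovered, the fit to the 2 groups compared has no interaction, and settings by score were not possible for the 10 min peaks, which carry none.

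With the replicate number as a block, counts rose to 2826 and 2745 genes for E2 in siControl and siFEN1 cells and to 872 and 703 for knockdown in vehicle and E2, and list calls from 20 to 36. Pairing removes the spread shared by libraries of a number. The block ended no call of a named gene, and no list call by camera with the preset correlation. With an estimated correlation it ended the calls of estrogen-repressed genes for E2, where camera gave adjusted p = 0.066 and 0.068. Beyond the values and counts printed beside the results the block changed no other call that the report names. Replicates 1 and 2 alone gave 1474, 148 and 115 genes for E2 in siControl cells and knockdown in vehicle and E2, and 2 for the interaction. Replicates 3 and 4 alone gave 1175, 1301, 335 and 354, and 2 for the interaction.

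The knockdown counts of 27 and 11 became 7 and 6 with no filter on low values, 9 and 3 by eBayes without trend, and 0 and 0 with only the groups compared, where E2 gave 417 and 293. Fewer libraries in the last setting leave fewer degrees of freedom, and the cause was not tested for the others. Quantile normalization gave 7 genes for knockdown in E2, and FEN1 there at -2.0 with adjusted p = 0.0659. Camera with an estimated correlation kept 6 of the 20 list calls, all for E2. By fry 14 of the 20 passed, histones among them (adjusted p = 0.031 in vehicle and 0.028 in E2), and the BCL2 family was lower with E2 as well (adjusted p = 0.0018 in siControl and 0.0012 in siFEN1 cells). The 6 that fry ended were all for knockdown: estrogen-induced, immediate early and interferon genes in vehicle, and replication, interferon and basal genes in E2.

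Leaving out 1 library gave 520 to 667 genes for E2 in siControl cells, 351 to 449 for E2 in siFEN1 cells, 0 to 10 and 1 to 5 for knockdown in vehicle and E2, 0 to 1 for the interaction (1 without siControl E2 replicate 3) and 20 to 28 list calls. Leaving out 1 library also ended 12 of 320 list values, all for knockdown: basal genes in E2 (without siControl E2 replicate 1, 2 or 3, siFEN1 vehicle 2 or 4, or siFEN1 E2 4), replication genes in E2 (siControl E2 1 or siFEN1 E2 3), and in vehicle estrogen-induced (siControl vehicle 3 or siFEN1 vehicle 2), immediate early (siControl vehicle 3) and interferon genes (siFEN1 vehicle 3). For E2 in siFEN1 cells, the count moved by over 1.5 times without siFEN1 vehicle replicate 3 (380) or 4 (386), or siFEN1 E2 replicate 1 (398) or 4 (351). For knockdown it did so without any 1 of the 8 libraries: in vehicle 1, 10, 8 and 2 without siControl replicates 1 to 4 and 0, 7, 2 and 6 without siFEN1 replicates, and in E2 3, 5, 2, 1 and 5, 5, 4, 5. FEN1 ranged from -2.29 to -1.84 in vehicle (adjusted p = 0.0343 to 0.10) and from -2.13 to -1.80 in E2 (adjusted p = 0.0737 to 0.169). With the block and a whole replicate left out, knockdown gave 181 to 411 genes in vehicle and 142 to 252 in E2.

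The relative E2 response of 0.870 was 0.842 with a pseudocount of 0.5, 0.920 with 8, 0.787 for means of at least 50 normalized counts, 0.823 with the block, and 0.781 for genes chosen in siFEN1 libraries. The reverse slopes were also under 1 in these settings, at 0.834, 0.894, 0.855, 0.997 and 0.866, so the slopes do not show that either response is smaller, and the cause of the moves was not tested.

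Kept peaks after knockdown were 32.1% when at least 50% of both peaks had to overlap, 34.8% by centres, 44.4% in the top 50% of scores and 65.9% with the same number of peaks. The 50% rule gave 23.6% at 30 min, 28.2% in proliferating cells and 31.6% for 10 min peaks, centres 28.4% in proliferating cells, and the same number of peaks 72.6% and 75.7% for the inhibitor. The 50% rule shares fewer peaks by construction. Repressed genes had an odds ratio of 0.831 with the 30 min list (exact p = 0.595), against 1.99, and the cause was not tested.

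Of 3317 alternative values for 158 named gene results, 2635 stayed on their side of the threshold, 682 no longer passed and 0 reversed. In simulated data, 1.5-fold changes were recovered in 8.96% of genes for E2 in siControl cells and 10.4% for knockdown in vehicle. About 67 genes changed per fold size there, fewer than were called for E2, and the adjustment is stricter when fewer genes change. These shares may therefore understate the recovery in the real E2 contrasts.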

Other observations

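The peaks near genes changed by the knockdown, and the genes named here from the blocked fit, were chosen after their values were seen.

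With the replicate block only, genes that rose with FEN1 knockdown in both hormone arms included TGM2, a transglutaminase (1.64 in vehicle and 1.74 in E2, blocked adjusted p = 0.00014 and 0.00012), CEACAM5 (1.62 and 1.65) and TNS4 (1.56 and 1.59). Of 529 genes higher with the knockdown in vehicle by the blocked fit, 51.8% had a siControl ERα peak within 20 kb, against 35.0% of other genes (odds ratio 1.99, two-sided Fisher's exact p = 8.2e-15). Of 339 lower genes the share was 36.6% (odds ratio 1.07, exact p = 0.566). In E2 the shares were 49.3% of higher genes (odds ratio 1.79, exact p = 4.5e-09) and 40.3% of lower genes (odds ratio 1.2, exact p = 0.0766). Genes are not independent replicates here.

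Kept shares near E2-induced genes were close to those of other peaks of equal score: 50.5% against 53.3% after knockdown, 43.4% against 43.1% at 30 min and 47.6% against 45.0% in proliferating cells. Near E2-repressed genes, 16.7% of 126 peaks in proliferating cells were kept with the inhibitor, against 28% of other peaks of equal score, and 46.9% against 40.2% after knockdown. At 30 min, 1 of 14 peaks near these genes was kept, or 7.14%, against 12.8% of other peaks of equal score. The FEN1 promoter carried a peak in the siControl and siFEN1 lists (siControl, chromosome 11, 61559883 to 61560561) and in none of the other 5.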
